A study of Mus musculus with 12 samples.

How the data were processed

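Total RNA of 12 embryoid body samples was labelled and hybridized to Affymetrix mouse expression arrays, 1 per sample, in 6 groups of 2 (WT, Smad4-null and Trim33-KD, each with activin or SB431542 for 2 h). The deposited values are log2 signals per probe set, per the labels; the antilog of each array has a mean of 500 after trimming 2% from either side, and the arrays were not quantile normalized. The summarization method is not given in the sources used here, and the authors' notes name limma without a version. The deposited log2 values were used unchanged, so no pseudocount entered and depth has no counterpart; the number of arrays sets the precision.

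The arrays hold 45101 probe sets, of which 64 are controls. A gene symbol was matched by the platform table to 34945 probe sets with exactly 1 symbol; 932 had several and 9160 none. The probe set with the highest mean over the 12 arrays stood for each of 18193 genes, of which 9010 had more than 1 probe set. Positions from the assembly GRCm38.p6 were used for gene names and gene order only.

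A means model with 1 coefficient per group was fitted to all arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior), and Benjamini-Hochberg adjustment over all genes with a threshold of 0.05 gave the calls. The groups share 6 residual degrees of freedom. The comparisons were activin minus SB431542 in each genotype, the 3 differences between these responses, and each mutant minus WT averaged over the treatments. Group tests used limma's camera with the preset correlation of 0.01 over 24 lists, adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Replicate numbers were not taken to pair arrays.

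The design, the lists and the rule for named genes were fixed before the data were examined. The rule names Smad4 and Trim33; in the WT response the 10 raised and the 10 lowered genes with the largest difference, in the other responses and response differences 5 in each direction, in the genotype differences 10 in each direction, among those past the threshold whose arrays do not overlap; all members of the Smad feedback, mesendoderm and nodal pathway lists in the responses; and up to 4 members of each other list. Further members named where a group is described were chosen after their values were seen. The lists were Smad feedback, mesendoderm factors, nodal pathway, mesoderm, extraembryonic endoderm, naive pluripotency, primed epiblast, neuroectoderm, trophectoderm, germ cell, BMP targets, TGF-beta matrix targets, Wnt targets, FGF and ERK targets, immediate early and stress genes, EMT and adhesion, hypoxia and glycolysis, p53 targets, cell cycle, fibroblast, interferon, imprinted, sex chromosome and housekeeping genes.

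Alternatives were quantile normalization, median centring, the upper 50% and 75% of genes by mean signal, the mean of a gene's probe sets, all probe sets, no cross-hybridizing probe sets, a trended and robust prior, array weights, only the groups compared, a replicate block in several forms, a change of at least 1.5-fold, and leaving out each array. Chosen after the data were seen were leaving out the arrays of narrow spread, a floor of 64 on the linear scale, and leaving out genes of chromosomes 8 and 14. The fit was tested on simulated data with changes set into 67, 67 and 66 genes of log2 size 1, 2 and 3. Of changes of 1 among the brighter genes, 68.7% were recovered in the WT response, 20.9% in a difference between responses and 91.0% in a genotype difference; of changes of 2 among the dimmer genes, 37.3%, 11.9% and 61.2%. With changes set among the brighter genes, 18, 5 and 8 unchanged genes were called in these comparisons. Many changed genes ease the adjusted threshold, so these shares are too high for comparisons in which few genes change. In the real WT response the brighter genes Irf1 (1.68) and Fzd10 (1.59) had limma adjusted p of 0.0791 and 0.0827 over all genes. In 192 list tests on unchanged simulated data 0 were called. The simulated noise was independent between genes, so these list tests could not show false calls that come from correlated genes. Probe sets with several symbols were left out.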

Results

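The cells were embryoid bodies, aggregates of differentiating mouse embryonic stem cells, harvested at day 2.5. They were wild type (WT), Smad4-null or carried a knock-down of Trim33 (Trim33-KD). Smad4 is the partner that receptor-activated Smad proteins share, and Trim33 is a nuclear ubiquitin ligase that binds Smad2 and Smad3. Embryoid bodies of each genotype received activin (ac, 50 ng/ml) or SB431542 (SB), an inhibitor of the type I activin and nodal receptors, for 2 h. The labels give SB431542 as 10 mM. No group was left untreated, so a gene called raised or lowered by activin is higher or lower than with SB431542. Such a difference can come from activin, from the inhibitor or from both. Each of the 6 groups had 2 Affymetrix arrays, 12 in all, and the number of arrays limits the precision of every value. The labels do not say whether replicates were separate cultures; if they were not, the p-values measure only the spread between these samples. The median log2 signal of an array lay between 5.85 and 6.30. The SD of log2 signal was 3.07 on WT-SB replicate 2 and 3.13 on Smad4-null-ac replicate 1, and 3.24 to 3.39 on the other arrays. The mean 18S rRNA signal was 5.53 on WT-ac replicate 1 and 5.82 on WT-SB replicate 1, against 7.56 to 10.2 on the other arrays, with the highest on Trim33-KD-SB replicate 2. The Actb 3' minus 5' log2 difference, a sign of RNA quality, was 0.74 on Trim33-KD-SB replicate 2 and 0.67 on WT-SB replicate 2, against 0.31 to 0.53 on the others.

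The genes named by the genotypes were read first. The brightest Trim33 probe set was 11.72 ± 0.16 in WT and 10.18 ± 0.23 in Trim33-KD (log2 mean ± SD, n = 4 each), so that 34.4% of the WT signal was left; a further Trim33 probe set left 30.3%. Trim33 fell by 1.54 on the log2 scale (SE 0.13, adjusted p = 0.0101, lower in 4 of 4 arrays). The 3 Smad4 probe sets kept 101%, 110% and 115% of the WT signal in Smad4-null arrays. The brightest Smad4 probe set was 12.17 ± 0.05 in Smad4-null and 11.96 ± 0.07 in WT arrays (log2 mean ± SD, n = 4 each). Where these probe sets lie relative to the mutated part of Smad4 is not given in the sources used here, so the Smad4 signal does not check that label.

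The series title asks which nodal and activin responses depend on Smad4 and on Trim33; the WT arrays give the reference response. In WT, activin raised 6 genes against SB431542. Smad7, an inhibitory Smad, rose by 3.11 on the log2 scale (8.64-fold, SE 0.27, n = 2 per group, adjusted p = 0.0222). Lefty1, a secreted nodal antagonist, rose by 2.81 (SE 0.24) and Fgf15, a secreted FGF, by 2.24 (SE 0.14). Pmepa1, which restrains Smad signalling, rose by 2.08 (SE 0.20), the homeobox gene Msx1 by 1.89 (SE 0.12) and the ephrin receptor gene Epha2 by 1.53 (SE 0.14). Both activin arrays lay above both SB arrays for each of them. The adjusted p was 0.00449 for Fgf15 and Msx1, 0.0222 for Lefty1 and Epha2 and 0.0303 for Pmepa1. No gene fell, and 731 genes had an unadjusted p under 0.05 in limma, where chance gives 910. Among the 9096 genes in the upper 50% of mean signal, 14 genes rose. They included Irf1 (1.68), the Wnt receptor gene Fzd10 (1.59), the nodal antagonist gene Lefty2 (1.20) and Myc (1.13), which were chosen after their values were seen.

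Of 13 measured Smad feedback genes, 3 rose (4 when adjusted over the list alone) and the list was called up with a median of 0.31 (camera adjusted p = 1.31e-09; adjusted p = 0.00946 with an estimated correlation). Of 11 BMP target genes, 1 rose (3 when adjusted over the list alone), and the median was 0.51 (adjusted p = 3.4e-08; adjusted p = 0.00946 with an estimated correlation). The BMP member that rose was Msx1. The 12 mesendoderm transcription factors were called up with a median of 0.45 (adjusted p = 1e-05), yet none rose over all genes and 1 did when adjusted over the list alone; the adjusted p was 0.171 with an estimated correlation. Among them, values were 2.08 for Gsc, an organizer homeobox gene, and 2.12 for Mixl1, a primitive streak homeobox gene. Wnt targets had a median of 0.25 (adjusted p = 5.46e-05; adjusted p = 0.0729 with an estimated correlation). Of 24 lists 10 were called, and the calls of Smad feedback and BMP targets alone held with an estimated correlation. Without the arrays of narrow spread, WT-SB replicate 2 and Smad4-null-ac replicate 1, the 6 genes had values of 1.37 (Epha2) to 2.84 (Smad7), adjusted p was 0.143 to 0.164 and 0 passed. The count was 0 without WT-SB replicate 2, WT-ac replicate 1 or WT-ac replicate 2, 2 to 4 without any single mutant array, and 13, of which 9 were raised and 4 lowered, without WT-SB replicate 1; 1 of 3 was lowered without either Smad4-null-SB array. With values floored at 64 on the linear scale, 3 genes were raised and 1 lowered, and Smad7, Lefty1 and Pmepa1 kept their values with an adjusted p of 0.0587.

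**Figure D1:**
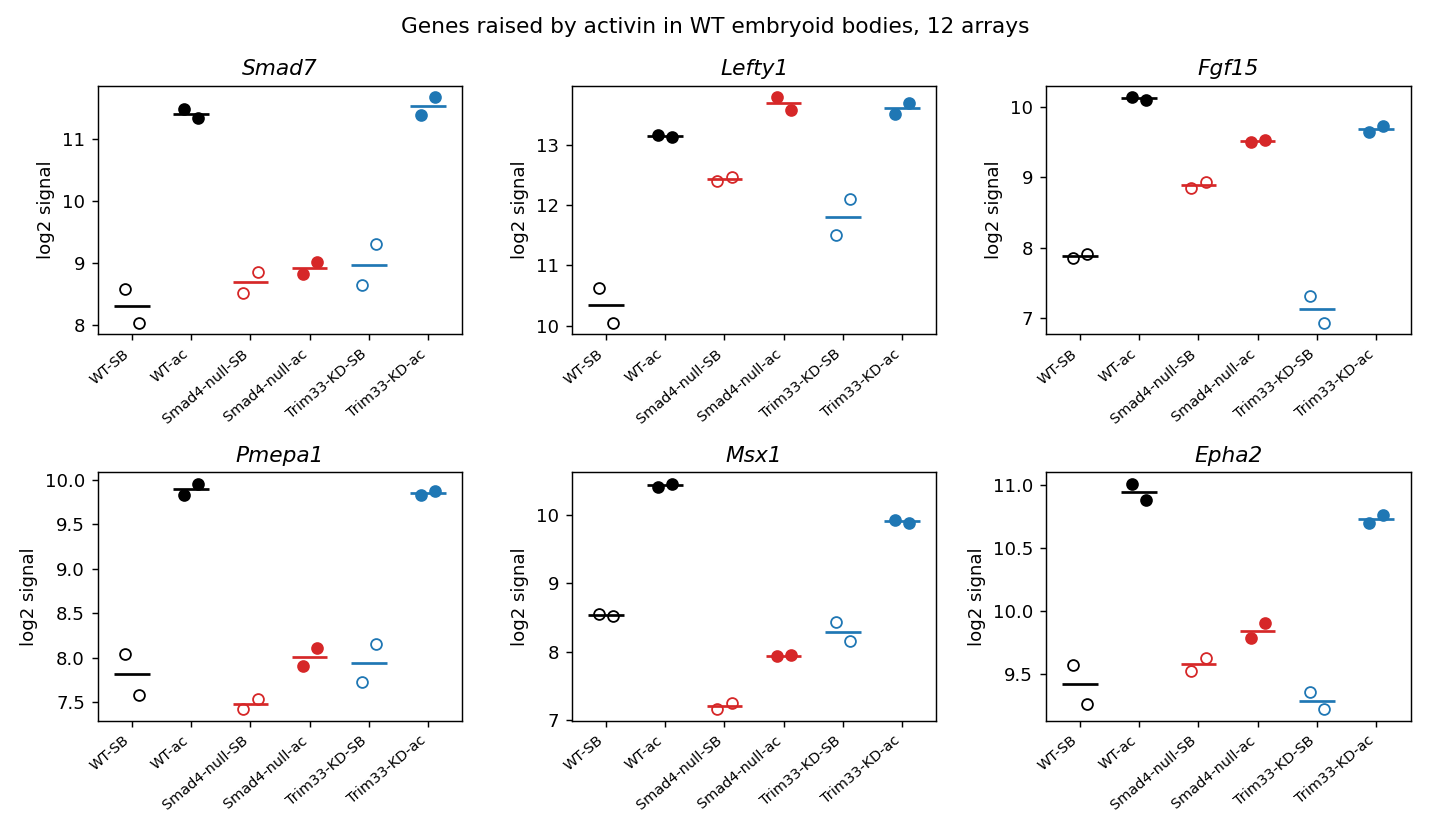
Log2 signal (vertical axes) of the 6 genes raised by activin in WT, in the 6 groups of 2 arrays; open circles are SB431542 arrays, filled circles activin arrays, and bars group means. The activin-minus-SB difference of Smad7 is 3.11 in WT, 0.23 in Smad4-null and 2.56 in Trim33-KD.

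The Smad4-null arrays address dependence on Smad4. The line and the genotype change together, so a different response cannot be assigned to the loss of Smad4 alone. The 6 genes raised in WT had smaller differences in Smad4-null embryoid bodies, with a median of 0.58 against 2.16 in WT (0.27 in Smad4-null for the genes called without WT-SB replicate 1). Smad7 had 0.23, Epha2 0.27, Lefty1 1.26, Msx1 0.74, Fgf15 0.63 and Pmepa1 0.52. None of these 6 passed in Smad4-null. Lefty1 and Fgf15 started from higher levels with SB431542 in Smad4-null (12.43 and 8.89) than in WT (10.33 and 7.88; log2 means, n = 2). The difference between the responses, Smad4-null minus WT, was -2.88 for Smad7 (SE 0.39), -1.61 for Fgf15, -1.55 for Lefty1, -1.55 for Pmepa1, -1.26 for Epha2 and -1.15 for Msx1. Its adjusted p ran from 0.226 to 0.376 over all genes; over these 6 genes alone it ran from 0.000312 to 0.00238, which is not independent evidence because the genes were chosen on the WT arrays. Over all genes 0 passed in limma, with 1317 at an unadjusted p under 0.05. Within the upper 50% of mean signal 4 passed: Fgf15, Smad7, Msx1 and Epha2 had the smaller response in Smad4-null.

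Activin lowered 2 genes in Smad4-null embryoid bodies and raised 0 in limma. Of 1239 genes at an unadjusted p under 0.05, 960 had a positive difference. This skew depended on the arrays and the scaling. The median of all genes was 0.06, but 0.03 without the arrays of narrow spread and -0.10 with median centring. Olfm2, which encodes a secreted olfactomedin protein, fell by 2.01 (adjusted p = 0.0139) and Plekhh3 fell by 1.72 (adjusted p = 0.0249). Both lay below the upper 50% of mean signal, where 0 genes passed in limma and 423 had an unadjusted p under 0.05. The Smad feedback list was called up with a median of 0.20 and 0 members rose (2 when adjusted over the list alone; camera adjusted p = 0.032; adjusted p = 0.458 with an estimated correlation). The p53 target list was called down with a median of -0.15 (adjusted p = 0.032; adjusted p = 0.681 with an estimated correlation). The response of Smad feedback genes was lower in Smad4-null than in WT by a median of -0.18 (adjusted p = 0.00463), and that of BMP targets by -0.37 (adjusted p = 0.00786); with an estimated correlation the adjusted p was 0.162 for each. The count of the response was 0 without Smad4-null-ac replicate 1, either Smad4-null-SB, WT-ac or Trim33-KD-ac array, 1 without either Trim33-KD-SB array, and 6 without Smad4-null-ac replicate 2. Its direction depended on the processing: 1 was raised and 5 lowered with quantile normalization, 4 raised and 5 lowered with array weights, and 11 raised and 0 lowered with values floored at 64, none of them shared with the 2 genes.

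The Trim33-KD arrays address dependence on Trim33. In Trim33-KD, activin raised Fgf15 by 2.56 (adjusted p = 0.00311) and Msx1 by 1.61 (adjusted p = 0.0143), both also raised in WT. Smad7 stood at 2.56, Pmepa1 at 1.91, Lefty1 at 1.81 and Epha2 at 1.44, and the median of the 6 genes was 1.86. These genes were chosen on the WT arrays, so a smaller median in another line, as in Smad4-null above, is partly a product of that choice; the genes raised in the mean response of the 3 genotypes had a median of 1.62 in Trim33-KD, 1.68 in WT and 0.57 in Smad4-null. The response of Lefty1 minus its WT response had a 95% interval of -1.80 to -0.20, and limma's adjusted p over these 6 genes was 0.128. For the other 5, Smad7, Fgf15, Pmepa1, Msx1 and Epha2, this difference lay between -0.55 (Smad7) and 0.32 (Fgf15); for Smad7 its 95% interval ran from -1.45 to 0.35. In the upper 50% of mean signal 13 genes rose, of which 12 rose in WT too, among them Irf1 (1.84), Fzd10 (1.55) and Lefty2 (1.21). Prdm1 (1.31), a repressor gene of primordial germ cells, passed in Trim33-KD alone; the difference between the genotypes did not pass for any gene.

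Smad feedback genes were called up in Trim33-KD with a median of 0.23 (0 of 13 rose, 5 when adjusted over the list alone; camera adjusted p = 2.34e-09; adjusted p = 0.00992 with an estimated correlation). BMP targets had a median of 0.65 (1 of 11 rose, 2 when adjusted over the list alone; adjusted p = 4.67e-08; adjusted p = 0.00992 with an estimated correlation). Mesendoderm factors had a median of 0.42 with none passing (camera adjusted p = 0.00107, and adjusted p = 0.263 with an estimated correlation). This median does not show whether single members such as Gsc and Mixl1 kept their WT difference. Between Trim33-KD and WT responses limma called 0 genes (2 without Trim33-KD-ac replicate 1), with 485 at an unadjusted p under 0.05, and camera called 0 of 24 lists. Against the Smad4-null response limma called 0 genes (1 without Trim33-KD-ac replicate 1), with 1117 at an unadjusted p under 0.05, and Fgf15 passed in the upper 50% of mean signal with a difference of 1.93. The response of Smad feedback genes exceeded that in Smad4-null by a median of 0.10 and that of BMP targets by 0.41 (adjusted p = 0.00867 each; adjusted p = 0.146 each with an estimated correlation). Across the upper 50% of genes, which are not independent replicates, the Trim33-KD and WT responses had a Pearson correlation of 0.503 (Spearman 0.304); over all genes it was 0.129 (Spearman 0.173). The count of 2 in Trim33-KD was 0 without Trim33-KD-ac replicate 2, 1 without WT-ac replicate 1, WT-ac replicate 2, Trim33-KD-SB replicate 2 or any Smad4-null array, and 0 without both arrays of narrow spread. Without Trim33-KD-ac replicate 1 it stayed at 2, but 1 rose (Fgf15) and 1 fell, and Msx1 did not pass.

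Embryoid bodies of the Smad4-null and WT lines were also compared apart from the treatment. The early mesendoderm program was low in Smad4-null: of 12 measured mesendoderm transcription factors 10 fell (10 when adjusted over the list alone), with a median of -1.73. Log2 differences were -4.38 for Gsc (SE 0.44) and -4.26 for Mixl1 (SE 0.32, n = 4 per genotype). With values floored at 64 on the linear scale they were -2.09 for Gsc and -4.09 for Mixl1. Unfloored, the primitive streak homeobox gene Evx1 had -4.23 (SE 0.36) and Lhx1, an organizer gene, -3.84 (SE 0.60). The T-box gene Eomes had -3.65 and Foxa2, an endoderm factor, -1.97, and all these factors passed. Of 13 naive pluripotency genes 10 rose and 2 fell (the same numbers when adjusted over the list alone), with a median of 0.94. The nuclear receptor gene Nr0b1 rose by 1.71, Fgf4 by 1.56, Klf4 by 1.52 and Prdm14 by 1.40, while the core factor genes Nanog (-0.38) and Pou5f1 (-0.31) fell. Of the naive genes that rose, Klf2 and Zfp42 lie on chromosome 8. Its brighter genes had a median of 0.21 in Smad4-null, and 0.42 in the last 3 of 8 equal runs of genes along it. Where Klf2 and Zfp42 lie relative to those runs is not given here. In camera the adjusted p was 1.03e-07 for the mesendoderm factors and 1.43e-06 for the naive genes, and the adjusted p was 0.151 for each with an estimated correlation.

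Targets of several pathways were low with the mesendoderm factors in Smad4-null. Among 10 Wnt targets 6 fell and 1 rose (7 and 2 when adjusted over the list alone; median -1.20, adjusted p = 0.00566; adjusted p = 0.156 with an estimated correlation). Sp5 (-6.68), a transcription factor gene activated by Wnt signals, fell most of all genes called; Cdx1 (-3.70), Dkk1 (-1.94) and Axin2 (-1.64) fell too, whereas Notum, a Wnt-inactivating enzyme gene, rose by 1.35. Among 10 FGF and ERK targets 7 fell and 1 rose (7 and 1 when adjusted over the list alone; median -0.77, adjusted p = 0.00302; adjusted p = 0.192 with an estimated correlation), with Fgf8 at -3.37. Among 11 BMP targets 6 fell and 1 rose (6 and 1 when adjusted over the list alone; median -0.87, adjusted p = 0.0144; adjusted p = 0.151 with an estimated correlation), with Id1 at -3.34. The nodal antagonist gene Cer1 (-3.42) and the gene of the activin-binding protein Fst (-4.72) fell, while Lefty1 rose by 1.32.

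In all, limma called 3356 of 18193 genes between Smad4-null and WT, 1295 raised and 2061 lowered. The most raised gene was Hprt, the purine salvage enzyme gene, at 12.72 ± 0.14 in Smad4-null against 6.15 ± 0.24 in WT (log2 mean ± SD, n = 4; difference 6.56, limma adjusted p = 1.24e-05, higher in 4 of 4 arrays). Adgrd1 (4.36), the hedgehog-binding protein gene Hhip (3.99) and the forebrain homeobox gene Lhx2 (3.66) were called too, but from low signals, and did not pass with values floored at 64. Further genes among the most lowered were Mid1 (-5.47), the apelin receptor gene Aplnr (-5.36), the cadherin gene Cdh11 (-4.62) and the Wnt agonist gene Rspo3 (-4.47). With the floor 6 of the 20 genes named for their size lost the call, and the difference was -2.09 for Gsc, -3.06 for Aplnr and -2.05 for Rspo3. A dim probe set of Mid1 had the opposite sign. The count was 2026 without both arrays of narrow spread, 2233 without WT-ac replicate 1 and 2121 without Smad4-null-SB replicate 2. The line and the genotype change together, so no gene of this comparison can be assigned to the loss of Smad4 alone.

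**Figure D2:**
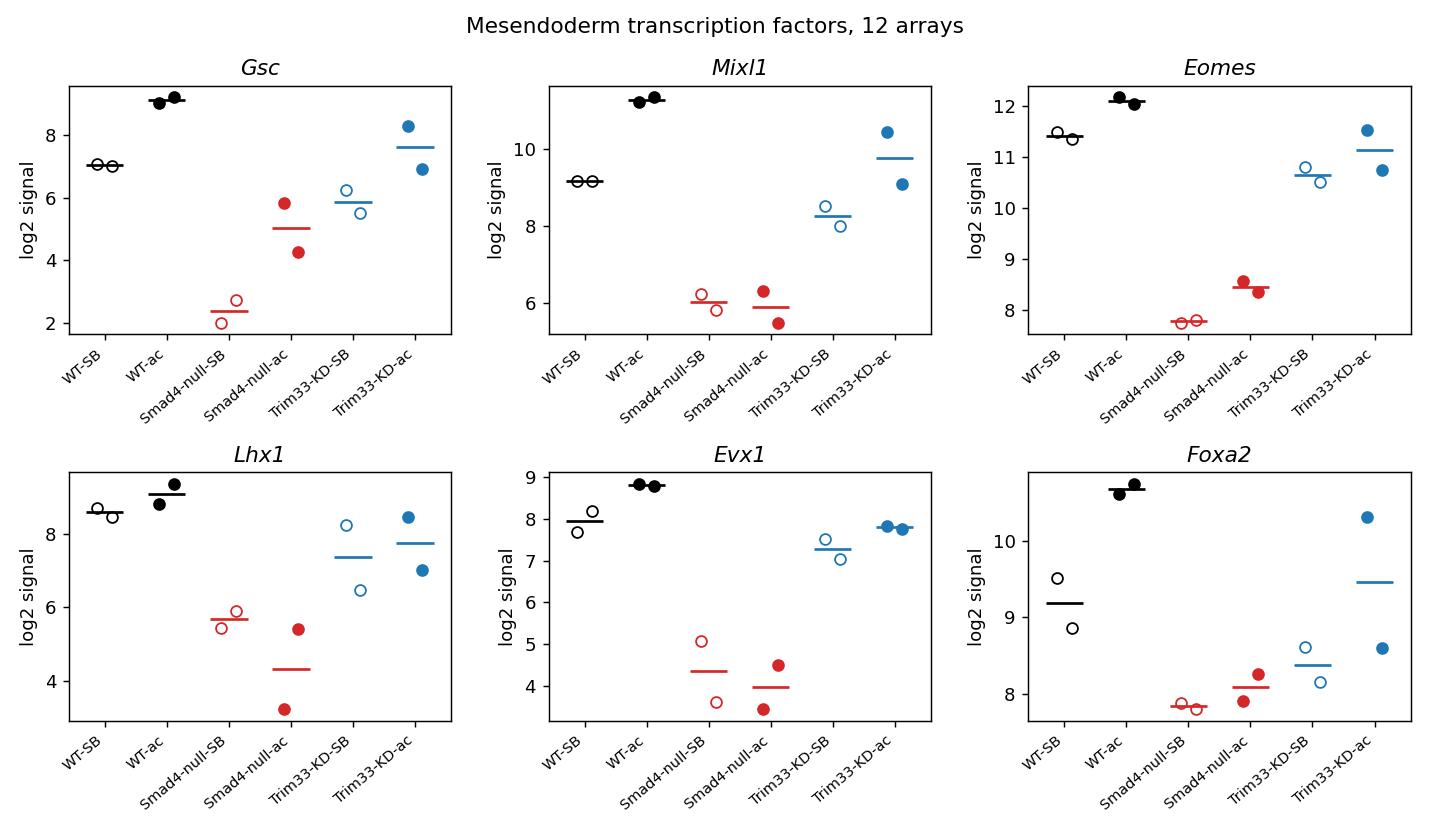
Log2 signal (vertical axes) of 6 mesendoderm transcription factors in the 6 groups of 2 arrays; open circles are SB431542 arrays, filled circles activin arrays, and bars group means. All 4 Smad4-null arrays lie below all 4 WT arrays for each factor, with differences of genotype means of -4.38 for Gsc and -1.97 for Foxa2.

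Genes of chromosomes 8 and 14 stood apart in the Smad4-null arrays, a comparison made after the values were seen. Among the upper 50% of genes by mean signal, those of chromosome 14 had a median difference of -0.54 from WT (304 genes) and those of chromosome 8 a median of 0.21 (522 genes), against -0.06 to 0.07 for the other chromosomes. Along chromosome 14, the last 5 of 8 equal runs of genes had a median of -0.76, or 59.2% of WT, and 156 of 190 genes were lowered. Along chromosome 8, the last 3 runs had a median of 0.42, or 133% of WT, and 106 of 196 genes were raised. The same runs had medians of -0.04 and 0.06 in Trim33-KD. An exact permutation test of each chromosome's median over the splits of 4 against 4 arrays gave p = 0.0286 for 9 chromosomes, 8 and 14 among them, the smallest this design allows (two-sided), or 0.0635 after adjustment over all chromosomes. Hhip, Cdh11, Klf2, Zfp42, Otx2, Zic2, Spry2 and Junb lie on these chromosomes.

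**Figure D3:**
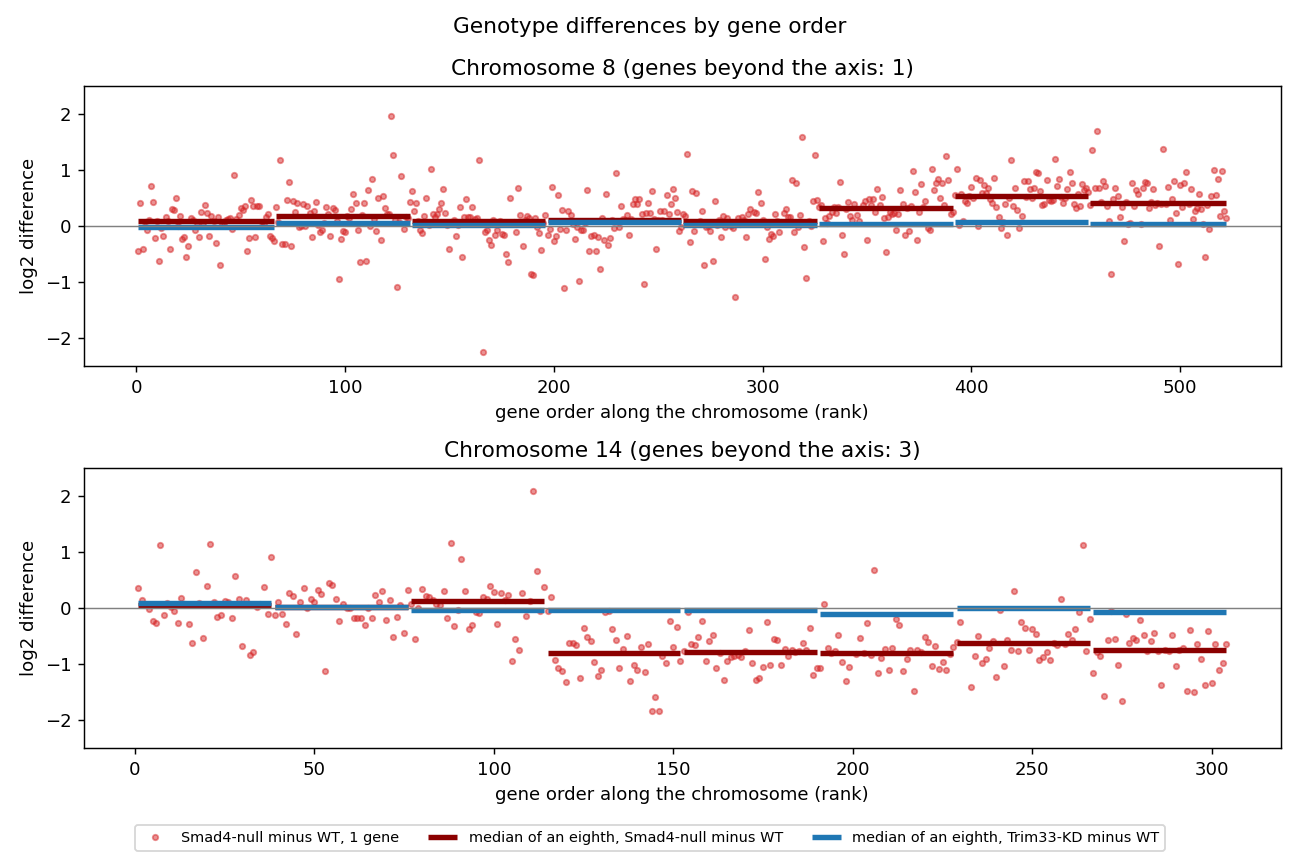
Log2 difference from WT (vertical axes) by gene order along chromosomes 8 and 14 (horizontal axes, rank); points are genes in Smad4-null, bars the medians of 8 equal runs of genes in Smad4-null (dark red) and Trim33-KD (blue). The last 5 runs of chromosome 14 have a median of -0.76 and the last 3 of chromosome 8 a median of 0.42 in Smad4-null.

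Trim33-KD embryoid bodies differed from WT apart from the treatment in 118 genes, 81 raised and 37 lowered. Chac1, whose enzyme degrades glutathione, rose by 2.00 (adjusted p = 0.0019), the stress-induced regulator gene Nupr1 by 2.68 and the stress transcription factor gene Atf3 by 1.21. Lowered genes included Trim33 (-1.54), the cyclin gene Ccnd2 (-1.11), the anterior homeobox gene Otx2 (-0.95) and Pax6 (-0.80), a neural factor. Larger differences came from low signals: Hhip (3.49, with a dim probe set of opposite sign), Bcl2l15 (3.40), the arginase gene Arg1 (2.76) and Usp26 (-3.90) did not pass with values floored at 64. Of the 20 genes named for their size, 12 lost the call with the floor, 15 without both arrays of narrow spread and 18 with only the groups compared. The 12 mesendoderm factors had a median of -0.94: 0 fell over all genes in limma, where 3087 genes had an unadjusted p under 0.05, and 6 fell when adjusted over the list alone (camera adjusted p = 0.000123; adjusted p = 0.646 with an estimated correlation). Eomes had -0.87 and Gata6 -1.03, and the lower values came with replicate 2 of Trim33-KD: Gsc was 8.31 and 6.93 on the activin arrays and Mixl1 10.43 and 9.09. The share of raised genes was 68.6%, but 81.0% with quantile normalization (119 raised, 28 lowered) and 90.2% with median centring (222 raised, 24 lowered), and 54.5% in the upper 50% of mean signal (429 raised, 358 lowered), 57.5% in the upper 75% and 58.7% with a trended and robust prior. With median centring the median of all genes moved from -0.04 to 0.16. The count fell to 21 without both arrays of narrow spread, to 10 without Trim33-KD-SB replicate 2, the array with the highest Actb 3' minus 5' difference (0.74), and to 15 without Trim33-KD-ac replicate 2; it was 29 to 55 without any other single array, except 103 without Trim33-KD-ac replicate 1.

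Smad4-null and Trim33-KD were each set against the same 4 WT arrays, so noise in those arrays enters both differences. In both, 36 genes rose, 19 fell and 16 moved in opposite directions. Independent calls would give 5.77, 4.19 and 11.8, and shared WT arrays with no real difference gave 0.02 raised in both and 0.02 lowered in both in simulation. That simulation holds no changed genes, so it is no reference for an overlap among real differences. The correlation of the differences across the upper 50% of genes was 0.303, against 0.498 simulated from the shared controls alone; with the WT arrays divided between the comparisons it was 0.170 and 0.175. Over all genes it was 0.321 against 0.499 simulated, and 0.00511 and 0.0843 with the WT arrays divided. Shared controls alone set the simulated correlation whatever the size of the noise, so it is no yardstick for differences that hold real changes. The covariance across the upper 50% of genes was 0.0363 against 0.00824 simulated, and 0.0216 and 0.0249 with the WT arrays divided. Over all genes the covariance was 0.0974 against 0.0662 simulated, and 0.00205 and 0.0315 with them divided.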

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

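Tests chosen only after the result was seen here are those without the arrays of narrow spread, apart from the correlation test, whose terms were written before its result.

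The difference between the responses of the Smad4-null and WT lines passed for 3 lists and between those of Trim33-KD and Smad4-null for 2. Smad4-null minus WT was -0.18 for Smad feedback genes, -0.37 for BMP targets and -0.25 for p53 targets (medians; adjusted p = 0.00463, 0.00786 and 0.00463 in camera). With an estimated correlation the adjusted p was 0.162, 0.162 and 0.522. Smad7 with -2.88 and Msx1 with -1.15 are members of the Smad feedback and BMP lists. Trim33-KD minus Smad4-null was 0.10 for Smad feedback genes and 0.41 for BMP targets (adjusted p = 0.00867 each; adjusted p = 0.146 each with an estimated correlation). Both differences depended on the processing. For Smad4-null minus WT, median centring ended the calls of Smad feedback genes (-0.45, adjusted p = 0.0603) and BMP targets (-0.65, adjusted p = 0.0947). It moved p53 targets to -0.53, still called. BMP targets had -0.61 with quantile normalization, -0.80 in the brighter 50% of genes and -0.10 with values floored at 64, called each time. Fry ended those of BMP targets (adjusted p = 0.111) and p53 targets (adjusted p = 0.417). BMP targets also lost the call without WT-ac replicate 1 (-0.09), WT-SB replicate 1 (-0.55) or Smad4-null-SB replicate 1 (-0.18). Single arrays also moved the medians. Without Smad4-null-ac replicate 1 they were -0.27 for Smad feedback genes, -0.57 for BMP targets and -0.11 for p53 targets, and without WT-ac replicate 2 they were -0.11, -0.69 and -0.16. BMP targets had -0.56 without WT-SB replicate 2. Without Smad4-null-ac replicate 2 BMP targets had -0.17 and p53 targets -0.39, and without Smad4-null-SB replicate 2 p53 targets had -0.45. Without the arrays of narrow spread the adjusted p was 0.0489 for Smad feedback genes, 0.0738 for BMP targets and 0.091 for p53 targets (-0.08). For Trim33-KD minus Smad4-null, BMP targets lost the call with the mean of probe sets (0.05, adjusted p = 0.155), all probe sets (adjusted p = 0.149), no cross-hybridizing probe sets (adjusted p = 0.0622), a genotype-by-replicate block (adjusted p = 0.0618) and fry (adjusted p = 0.166). They also lost it without Trim33-KD-ac replicate 2 (0.10), Trim33-KD-SB replicate 2 (0.40) or Smad4-null-SB replicate 1 (0.43), and had 0.62 without Trim33-KD-ac replicate 1. Smad feedback genes lost it with fry (adjusted p = 0.052) and without Smad4-null-SB replicate 2 (0.13); their median ran from 0.06 without Trim33-KD-ac replicate 1 to 0.34 in the brighter 50% of genes. It was 0.24 without Trim33-KD-SB replicate 1, 0.26 without Trim33-KD-ac replicate 2, 0.22 without Smad4-null-SB replicate 1, and 0.17 and 0.19 without Smad4-null-ac replicates 1 and 2.

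Probe sets with no gene name, which no gene comparison uses, also differed: 319 of 9160 passed between Smad4-null and WT, 151 raised and 168 lowered, and 8 between Trim33-KD and WT. In the 3 responses 0 passed in limma.

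Across the upper 50% of genes the responses of Smad4-null and WT had a negative Spearman correlation of -0.30 (-0.22 over all genes, which are not independent replicates). Yet 55.9% of the 177 genes with an unadjusted p under 0.05 in WT had the same sign in Smad4-null, and 65.2% of the 115 raised ones. Over all genes these shares were 40.5% of 731 and 64.8% of 264. Without WT-SB replicate 2 and Smad4-null-ac replicate 1, the arrays of narrow spread, the correlation across the upper 50% was 0.217 (Pearson 0.234). That value argues against an opposite response without Smad4 as the source of the negative value. Leaving out WT-SB replicate 2 alone gave 0.168 and Smad4-null-ac replicate 1 alone -0.11. The narrow spread of these arrays stays open as an explanation, but leaving them out cannot part it from their other traits. WT-SB replicate 2 had an Actb 3' minus 5' difference of 0.67. The mean correlation with the other arrays was lowest on these arrays, at 0.961 for WT-SB replicate 2 and 0.956 for Smad4-null-ac replicate 1. Without them, WT-SB and Smad4-null-ac each keep 1 array.

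The real division of the 8 arrays of Smad4-null and WT into 4 and 4 called 3493 genes in a fit of these groups alone, and the highest of the other 34 divisions called 3. For Trim33-KD and WT the real division called 125 and the highest other 15, which parted activin from SB431542 arrays. In each case 1 of 35 divisions, the real one, called as many genes, the smallest share these divisions can give. The first rank of the real division argues against a chance division for the 3493 and the 125 in this fit, which ignores the treatment. It does not exclude chance, and it cannot part the genotype from the line or the culture. With the treatment kept and only these groups fitted, Trim33-KD against WT counted 2, so the 125 says little of which genes differ.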

How the results depend on the processing

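Of the alternatives run, leaving out the narrow arrays, the floor and leaving out genes of chromosomes 8 and 14 were chosen after seeing the data. No value of a gene followed by name turned its sign under these alternatives while either setting called it. No called list turned the direction of its test where the alternative called it too. Turns of a list in an alternative that did not call it were not counted. Counts of genes changed direction with the floor. Counts of the 3 responses are small and changed with the set of genes tested and with single arrays. The cause was not tested, except that fewer genes are tested in the brighter sets and fewer arrays used in the fits of only the groups compared and without arrays. A pseudocount alternative was not run, since the values are log2 already.

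In the order WT, Smad4-null and Trim33-KD, responses counted 14, 0 and 13 in the brighter 50% of genes, 2, 0 and 1 with all probe sets, 13, 0 and 13 with the trended and robust prior, and 0, 0 and 0 with only the groups compared or with a genotype-by-replicate block. WT counted 2 with median centring or a replicate block, 11 in the upper 75% and 0 without the narrow arrays. Smad4-null counted 6 with quantile normalization, 9 with array weights, 4 with a random block and 11 floored at 64, all 11 raised where the 2 of the unfloored values were lowered. Trim33-KD counted 9 in the upper 75%, 7 with a random block or floored, 1 with the mean of probe sets or no cross-hybridizing ones, and 0 without the narrow arrays. The Smad4-null minus WT response difference counted 4 in the brighter 50% and 2 with trend and robust, all lowered, but 11 floored, all raised; Trim33-KD minus WT 2 floored; Trim33-KD minus Smad4-null 1 raised in the brighter 50% or with trend and robust, 1 lowered with all probe sets, and 11 floored, 1 raised and 10 lowered.

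Smad4-null against WT counted 2208 at 1.5-fold or more and 2026 without the narrow arrays. Trim33-KD against WT counted 246 with median centring, 787 in the brighter 50%, 351 in the upper 75%, 51 with all probe sets, 637 with trend and robust, 2 with only the groups compared, 65 with array weights or a random block, 230 floored, 52 with the mean of probe sets and 21 without the narrow arrays. The median of the WT-raised genes was 0.68 in Smad4-null with all probe sets or a replicate block and 0.69 with the mean of probe sets; in Trim33-KD it was 2.08 with median centring, 1.53 in the brighter 50%, 1.62 in the upper 75%, 2.09 with all probe sets or a replicate block, 1.61 with trend and robust or floored, and 1.62 with the mean of probe sets or for genes raised in the mean response. For these medians the WT-raised genes were chosen anew in each setting: 2 with all probe sets or a replicate block, and 14 in the brighter 50%. The medians thus cover different sets of genes and do not show that the response of the same 6 genes moved. The mesendoderm call in the WT response (median 0.45) was lost with an estimated correlation (adjusted p = 0.171) and with fry (adjusted p = 0.403). Median centring moved the median of all genes from 0.11 to -0.17 in the Smad4-null minus WT response difference, from 0.06 to -0.10 in the Smad4-null response and from -0.05 to 0.07 in the WT response.

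Leaving out each array gave 0 to 13 genes in the WT response, 0 to 6 in Smad4-null, 0 to 3 in Trim33-KD, 0 to 0 for Smad4-null minus WT, 0 to 2 for Trim33-KD minus WT and 0 to 1 for Trim33-KD minus Smad4-null. Smad4-null against WT ran from 2121 to 3132 and Trim33-KD against WT from 10 to 103. The WT-raised genes ran from 0.27 to 0.73 in Smad4-null and from 1.61 to 2.24 in Trim33-KD over 9 fits; without WT-ac replicate 1, WT-ac replicate 2 or WT-SB replicate 2 no WT gene was called and there was no median. The Smad feedback list ran from 0.17 to 0.31 and the mesendoderm list from 0.41 to 0.56, both called in 12 of 12 fits. The WT-raised genes were chosen anew in each of these fits, so their medians cover different sets of genes. An arm left with 1 array was assumed to vary like the other groups. The labels do not say that replicate numbers pair arrays, so they were not taken to. Deviations of arrays with the same replicate number correlated at 0.385 in WT, -0.192 in Smad4-null and 0.335 in Trim33-KD across genes. Of 12 pairs of groups of different genotypes, 4 had a correlation over 0.1. A shared replicate effect in WT and Trim33-KD therefore stays possible, and with a genotype-by-replicate block each response counted 0 genes.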

Other observations

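The tests on chromosomes 8 and 14, on their signal and on Hprt were chosen only after the result was seen; the tests on ATF4 targets were written before.

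Among germ cell genes, Dazl rose by 1.53 and Prdm1 by 0.95 in Smad4-null, and the meiotic gene Sycp3 fell by 1.37. Among immediate early and stress genes 5 of 14 fell in Smad4-null (7 fell and 1 rose when adjusted over the list alone; median -0.61, adjusted p = 0.0144; adjusted p = 0.151 with an estimated correlation), with Fos down by 1.37 and Egr1 by 1.12. Among p53 targets 4 of 9 fell (7 when adjusted over the list alone; median -0.41, adjusted p = 0.00289; adjusted p = 0.192 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1a down by 0.97. Sex chromosome genes had a median of 0.55 and 2 of 4 rose (3 when adjusted over the list alone; adjusted p = 0.0194; adjusted p = 0.192 with an estimated correlation); both that rose, Xist and Kdm5d, have a dim probe set of opposite sign. The primed epiblast list had a median of 0.14 in Smad4-null: Fgf5 fell by 1.43 and Pou3f1 rose by 0.92. The nodal pathway list had a median of -0.12, with Tdgf1, the nodal co-receptor gene, down by 0.70 and Gdf3 up by 1.10.

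In the WT response the lists of primed epiblast (0.07), naive pluripotency (0.05), nodal pathway (0.11) and p53 targets (0.12) were called up (adjusted p = 0.0331 each), with adjusted p = 0.158, 0.395, 0.158 and 0.395 with an estimated correlation. TGF-beta matrix targets were called up with a median of -0.04 and a mean of 0.13, which differ in sign, and hypoxia and glycolysis genes down with a median of -0.23 (adjusted p = 0.0437 each; adjusted p = 0.171 and 0.468 with an estimated correlation). In Trim33-KD primed epiblast (0.08), Wnt targets (0.16), TGF-beta matrix targets (0.01), trophectoderm (0.20) and fibroblast genes (0.22) were called up, with adjusted p of 0.196 to 0.263 with an estimated correlation. Lists called in none of the 8 comparisons had these medians in Smad4-null against WT: germ cell 0.42, EMT and adhesion -0.41, neuroectoderm -0.05, imprinted -0.29, mesoderm -0.39, extraembryonic endoderm -0.21, interferon 0.27, cell cycle 0.05 and housekeeping -0.04.

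Genes low in Smad4-null form a block on chromosome 14, and genes high in it a block on chromosome 8. Among genes of the next 25% of mean signal, which did not define the block, 72.7% of 110 past its start on chromosome 14 and 49.1% of 53 before it were lower; a copy number difference may give this, as would shared regulation of the region, and the medians past and before it were -0.36 and 0.01, against -0.28 and -0.17 in Trim33-KD. The block's median difference was -0.73 relative to genes of equal mean signal elsewhere, which argues against the signal range of the arrays. Without genes of chromosomes 8 and 14, 2791 of the 3356 genes still passed, so these chromosomes do not account for the wide difference. Hprt, 6.56 higher in Smad4-null, could reflect a different parental line, but the line and the genotype change together and cannot be told apart.

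Chac1 and Nupr1 stood out in Trim33-KD, so a list of 26 ATF4 target genes was written down from general knowledge (Trib3 and Sesn2 are also in the stress and p53 lists, whose values had been tabulated). Of 25 measured, 23 had a positive difference from WT, with a median of 0.44 (camera p = 9.46e-16; p = 0.00937 with an estimated correlation); Asns with 0.73 and Psat1 with 0.67 rose and none fell, which is consistent with a rise of ATF4 targets. The same genes had a median of 0.27 in Smad4-null against WT; 18 of the 25 were positive, 8 rose and 1, Sesn2, fell by 0.90, so a low level in the WT arrays, where WT replicate 1 arrays also had the lowest 18S signal, could account for part of the rise. The Trim33-KD median was 0.56 between the arrays numbered 1 and 0.38 between those numbered 2, and both explanations stay open.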
